A study of Homo sapiens with 24 samples.

How the data were processed

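Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in human CD14-positive monocytes. Per the labels, the cells were purified from buffy coats and kept overnight in medium with M-CSF, a growth factor of the monocyte lineage. The 24 libraries form 6 groups of 4: unstimulated cells (Rest), IL-10, LPS, IL-10 with LPS, TNF, and IL-10 with TNF. Groups were taken from the sample titles and their treatment tags. The treatment protocol in the labels names another cytokine in place of IL-10 and more than one duration, so no dose or duration of treatment is used here. Replicates are numbered in the labels, which do not say whether a number stands for a donor. The columns of the deposited table put the letter D before the same numbers, and its meaning is not given in the sources used here.

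Per the submitters' processing notes, Bowtie2 and MACS2 were used and the genome build was GRCh38 (hg38), and their versions and settings are not given in the sources used here. The authors deposited 1 list of 73341 merged peaks and 1 table of normalized values with a column per library. The deposited values are log2 values: back-transformed, each column sums to between 977582 and 1004754, nearly the same total in every library. How reads were filtered, shifted for the transposase and counted is not given in the sources used here. The depth of each library is unknown and cannot be recovered, because no whole reads could be read back from the values, so no counting interval is given for a peak. Within each replicate number, the mean deviation from the group means was 0 for the peaks to within 2.1e-14, which shows that an additive term per number had been removed before deposit.

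The 138 peaks on the Y chromosome were left out, and the other 73203 peaks, on chromosomes 1 to 22 and X, were tested. Their median width was 532 bp (range 150 to 4150). Each peak was assigned to the nearest protein-coding gene span (distance 0 when inside it) within 50 kb, with gene coordinates of the same build; 63455 peaks (86.7%) had such a gene and 39959 (54.6%) lay inside one. The plan had been to use the nearest transcription start, but the gene table used here has no strand, so gene spans were used, and the strand of the promoter genes came from general knowledge. Gene models named by a locus number alone were left out. A gene named for a peak is its nearest gene, not a shown target. Positions are 1-based and on GRCh38.

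The values were tested as deposited in limma 3.58.1 (R 4.3.3), in 1 fit of all 24 libraries with a mean per group, without a filter or pseudocount, with empirical Bayes moderation that follows the mean, and with Benjamini-Hochberg adjustment over all tested peaks within a contrast. The fixed plan had named a pseudocount for values on a linear scale, which log2 values do not need. Peaks with an adjusted p under 0.05 are called changed. The comparisons are LPS, TNF and IL-10 alone against Rest, IL-10 with LPS against LPS, and IL-10 with TNF against TNF, and 3 interactions compare the effect of IL-10 between the stimulation states. Errors beside log2 changes are the standard errors of this fit (n = 4 libraries per group). The p-values measure the spread left between these libraries after the additive term per replicate number had been removed.

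The fixed fit has no term for the replicate number. The removed terms show that the authors treated the numbers as a shared factor, so the libraries are taken as paired here. The usual check is void because of that removal: deviations of the 60 same-numbered pairs of libraries correlated by a median of -0.197 (range -0.475 to 0.166). The fit without a block also counts 18 residual degrees of freedom where 15 are left, and so its p-values and standard errors are too small. For LPS against Rest the median standard error was 0.137 without the block and 0.151 with it. Counts over all peaks from the fit with the replicate number as a block are therefore printed beside the others. The peak counts of gene lists are from the fit without it.

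Both fits were tested on simulated data with 200 changed peaks among 73203. For LPS against Rest, 7.43% of unchanged peaks had p under 0.05 without the block and 5.05% with it, and false calls were 24.5% and 9.09% of the calls. For IL-10 with LPS against LPS these values were 7.47% and 5.03%, and 21.4% and 8.28%. The false share depends on how many peaks change, and far more were called in the real data. These false shares therefore do not carry over to the counts reported here. In the fit without the block, log2 changes of 0.5, 1 and 2 were recovered in 36%, 83% and 100% of the peaks for LPS against Rest, and in 40%, 84% and 100% for IL-10 with LPS against LPS.

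Gene lists were fixed before the data were examined: interferon-stimulated genes; inflammatory cytokines, chemokines and effectors; NF-kB pathway genes; interferon regulatory factors; known IL-10 and STAT3 response genes; AP-1 and MAF family factors; antigen presentation genes; tissue-resident type macrophage genes; glycolysis genes; monocyte identity genes; housekeeping genes. Markers of T cells, B cells, NK cells, granulocytes, and platelets and erythroid cells stood for cells that a CD14 selection could carry along. Some genes are in more than 1 list. The peaks of each list were tested against all other peaks with camera in limma (preset correlation 0.01), adjusted over the 80 tests of 16 lists in 5 comparisons, again with an estimated correlation, and with fry. Peaks of 1 gene are not independent.

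The rule for named peaks was also fixed before the data were examined. It took the peaks with the largest changes in each direction whose 4 values in one group all lie on 1 side of those in the other, at most 1 per gene, the leading genes of each list by adjusted p, the promoter peak (within 1 kb of the start) of IRF1, IRF5, IRF8, SOCS3, TNF, IL6, IL12B, IL1B and CXCL10, and the leading peaks of each interaction. IL12B had no peak within 1 kb of its start, the nearest lying 1221 bp away. Gene models with only a locus number were passed over. A few items that this rule takes are not reported here.

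Peaks called higher with LPS or TNF by a log2 change of at least 1 are called induced here. The share of them that IL-10 lowered was set beside that of other peaks (by gene list with Fisher's exact test, repeated with the block after the results without it were seen), and once more with separate stimulated libraries in each comparison. Alternatives were the replicate block, pseudocounts of 0.1 and 5 on the linear scale, quantile normalization, centring every library on its median, library weights, removal of the peaks with the lowest means, a fit of only the groups compared, a log2 change of at least 1, and leaving out each library. Motif searches were not run because no genome sequence was used here, and no count test was run because the values are not counts. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.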

Results

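Open chromatin was profiled by ATAC-seq in human CD14-positive monocytes that were left unstimulated (Rest) or treated with IL-10, LPS, TNF, IL-10 with LPS, or IL-10 with TNF, with 4 libraries per group and 24 in all. IL-10 is an anti-inflammatory cytokine that signals through STAT3. LPS is a bacterial cell wall component sensed by TLR4, and TNF is an inflammatory cytokine. The study asked how IL-10 regulates the responses to LPS and TNF, and its title names the transcription factors IRF1 and IRF5. Accessibility is given as log2 normalized values over 73203 peaks, and the depth behind them is unknown. The peak named for a gene differs between some comparisons (FOSL2, IL27, IRF1, IRF2, LIPA, MAF, NLRC5, SOCS3, STAB1, TNIP1, ZFP36L2, and CXCL8 also within a comparison). Values of these genes therefore do not compare treatments at 1 site.

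Within groups, pairs of libraries correlated over the peaks by 0.942 to 0.990, and pairs from different groups by 0.693 to 0.974. The first principal component held 67.1% of the variance and separated the LPS and TNF libraries from the unstimulated ones. The second held 13.3%, with the libraries treated with IL-10 on one side and those without it on the other.

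**Figure D1:**
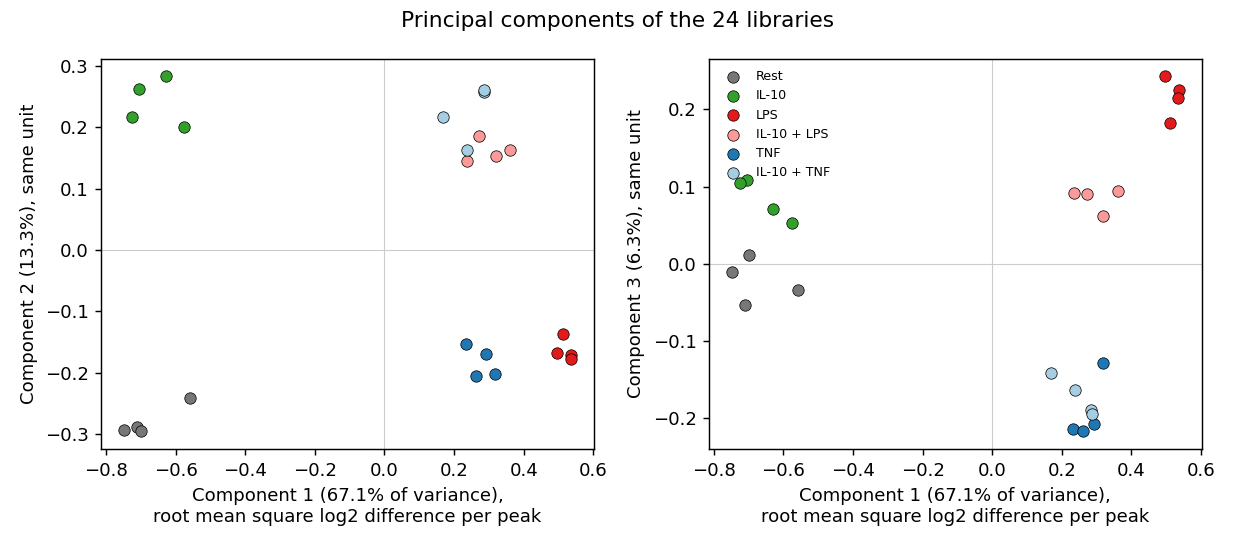
Principal components of the 24 libraries, each point a library coloured by group; axes are root mean square log2 differences per peak, with the first component (67.1% of variance) against the second (13.3%) on the left and the third (6.3%) on the right. On the second component the libraries with IL-10 lie between 0.145 and 0.283 and those without it between -0.296 and -0.137.

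LPS against Rest asks which regions open or close in the inflammatory response. The largest rise was inside SOD2, which encodes mitochondrial superoxide dismutase (6.62 ± 0.19 on the log2 scale, 98.5-fold, adjusted p = 2.1e-20, limma; chromosome 6, 159676318 to 159678925). A peak inside IL1B, the gene of the cytokine interleukin-1 beta, rose by 6.23 ± 0.22 (74.9-fold; chromosome 2, 112828797 to 112830730), and a peak 18424 bp from CXCL8, which encodes a neutrophil chemokine, rose by 6.23 ± 0.33. Peaks nearest NDP (6.43 ± 0.68, chromosome X, 32827 bp away) and inside WDFY1 (6.09 ± 0.25) completed the largest rises. The largest falls were next to EGR1, an immediate early transcription factor (-5.16 ± 0.30; chromosome 5, 138469322 to 138471156), and near SLC46A2 (-4.43 ± 0.23), CCDC152 (-4.10 ± 0.43), the tetraspanin gene CD9 (-3.81 ± 0.18) and PRUNE2 (-3.70 ± 0.31).

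Interferon-stimulated genes opened with LPS: 178 of the 217 peaks assigned to them rose and 20 fell (178 and 21 adjusted over the list alone), among them peaks at the antiviral gene OASL (2.94 ± 0.11) and the GTPase gene GBP5 (4.41 ± 0.16). The list median was 1.40 (camera adjusted p = 2.06e-16, and adjusted p = 0.0383 with an estimated correlation). Of 158 peaks at inflammatory cytokine, chemokine and effector genes, 119 rose and 15 fell (120 and 15 adjusted over the list alone). Those that rose included a peak near IL27 (2.86 ± 0.09) and another peak near CXCL8 than the one above (4.38 ± 0.14). The inflammatory list had camera adjusted p = 5.18e-13, and adjusted p = 0.0965 with an estimated correlation. At NF-kB pathway genes 168 of 218 peaks rose and 25 fell (168 and 25 adjusted over the list alone), as at the inhibitor TNIP1 (4.10 ± 0.12) and at TRAF1 (2.27 ± 0.07). The NF-kB list had camera adjusted p = 3.11e-17, and adjusted p = 0.0965 with an estimated correlation. Known IL-10 and STAT3 response genes had 187 of 293 peaks higher and 62 lower (187 and 63 adjusted over the list alone), with peaks at TNIP3 (2.80 ± 0.09) and the feedback inhibitor SOCS3 (3.19 ± 0.10) among them (camera adjusted p = 1.19e-07; adjusted p = 0.286 with an estimated correlation). At interferon regulatory factors 46 of 85 peaks rose and 23 fell (46 and 23 adjusted over the list alone), including a peak 7608 bp from IRF1 (5.53 ± 0.23) and one near IRF2 (1.98 ± 0.09). The interferon regulatory factor list had camera adjusted p = 0.0104, and adjusted p = 0.318 with an estimated correlation.

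Tissue-resident type macrophage genes closed with LPS, with 81 of 115 peaks lower and 16 higher (81 and 16 adjusted over the list alone), as at the transcription factor gene MAF (-2.21 ± 0.10) and the scavenger receptor gene STAB1 (-1.53 ± 0.07). Another peak in MAF rose (3.11; chromosome 16, 79372215 to 79373015). The macrophage list had camera adjusted p = 1.43e-06, and adjusted p = 0.275 with an estimated correlation. Antigen presentation genes had 64 of 130 peaks lower and 40 higher (64 and 40 adjusted over the list alone; camera adjusted p = 0.0478, and adjusted p = 0.580 with an estimated correlation), with a fall at CD74 (-1.85 ± 0.09), the class II invariant chain, beside a rise at the class I regulator NLRC5 (3.86 ± 0.15). Glycolysis genes had 73 of 138 peaks higher and 38 lower (73 and 38 adjusted over the list alone; camera adjusted p = 0.0068, and adjusted p = 0.286 with an estimated correlation). The AP-1 and MAF family (52 higher and 80 lower of 152, camera adjusted p = 0.357), monocyte identity genes (46 and 60 of 128, adjusted p = 0.643) and housekeeping genes (18 and 14 of 47, adjusted p = 0.475) were not called as lists. Even so, the AP-1 factor genes BATF (5.40 ± 0.21) and FOSL2 (2.05 ± 0.07) had peaks that rose. The counts of these 3 lists adjusted over the list alone were 52 and 80, 46 and 61, and 18 and 14. No marker list of other blood cells was called with LPS. The camera adjusted p was 0.632 for T cells, 0.243 for B cells, 0.402 for NK cells, 0.166 for granulocytes, and 0.361 for platelets and erythroid cells.

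Promoter peaks of CXCL10 (3.43 ± 0.15), IL1B (2.53 ± 0.11), SOCS3 (2.26 ± 0.12), IL6 (1.80 ± 0.20), TNF (0.86 ± 0.11) and IRF1 (0.45 ± 0.07) rose with LPS. That of IRF5 fell (-0.30 ± 0.09, adjusted p = 0.0026), and that of IRF8 was not called (0.15 ± 0.09, adjusted p = 0.128). Of the 12896 peaks within 1 kb of a gene end, 6.41% rose by a log2 change of at least 1, against 21.6% of the other 60307. In all, 26827 peaks rose and 28358 fell (25940 and 27260 with the replicate number as a block), of which 13872 and 11244 changed by at least 1 on the log2 scale. After quantile normalization the latter were 11839 and 13131, so the majority at this size depends on the scaling.

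TNF against Rest asks the same of a host cytokine. The largest rises were again at IL1B (6.24 ± 0.22, 75.7-fold, adjusted p = 1.66e-18, limma), CXCL8 (6.14 ± 0.33) and SOD2 (5.84 ± 0.19), and also at TNNI1 (5.92 ± 0.25; chromosome 1, 201403868 to 201404511) and RFTN1 (5.83 ± 0.38). The largest falls were at CCDC152 (-4.44 ± 0.43), ZFP36L2, which encodes an RNA-binding protein that promotes mRNA decay (-3.78 ± 0.23), SELENOP, the gene of the plasma selenium carrier (-3.45 ± 0.34), SLC46A2 (-3.45 ± 0.23) and PRUNE2 (-3.41 ± 0.31).

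Inflammatory genes opened with TNF, with 124 of 158 peaks higher and 8 lower (124 and 8 adjusted over the list alone). The inflammatory list had camera adjusted p = 5.06e-19, and adjusted p = 0.0603 with an estimated correlation. Another peak near CXCL8 than the one above rose by 5.45 ± 0.14. At NF-kB pathway genes 171 of 218 peaks rose and 14 fell (171 and 14 adjusted over the list alone), including peaks at TNIP1 (3.86 ± 0.12) and TNFAIP8 (4.51 ± 0.15). The NF-kB list had camera adjusted p = 4.82e-19, and adjusted p = 0.0801 with an estimated correlation. Interferon-stimulated genes had 160 of 217 peaks higher and 23 lower (163 and 24 adjusted over the list alone), such as IFI6 (2.56 ± 0.10) and GBP5 (3.51 ± 0.16). The interferon-stimulated list had camera adjusted p = 3.16e-12, and adjusted p = 0.0734 with an estimated correlation. The lists of interferon regulatory factors (42 higher and 23 lower of 85; IRF1 distal peak 5.57 ± 0.23 and IRF2 3.06 ± 0.17) and of known IL-10 and STAT3 response genes (161 and 67 of 293; S100A8 3.39 ± 0.13) were called higher. Their camera adjusted p was 0.0244 and 3.71e-04, but adjusted p = 0.394 and adjusted p = 0.487 with an estimated correlation. Adjusted over the list alone, these counts were 42 and 23, and 162 and 68. Tissue-resident type macrophage genes had 76 of 115 peaks lower and 12 higher (77 and 12 adjusted over the list alone; camera adjusted p = 3.95e-07, and adjusted p = 0.275 with an estimated correlation), with STAB1 lower (-1.58 ± 0.13) and a peak in MAF higher (2.95 ± 0.16).

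Antigen presentation (35 higher and 57 lower of 130, camera adjusted p = 0.243; TAPBP 1.67 ± 0.08, NLRC5 2.18 ± 0.12), glycolysis (64 and 37 of 138, adjusted p = 0.112), AP-1 and MAF family (49 and 68 of 152, adjusted p = 0.368; MAFF 2.99 ± 0.14, FOSL2 3.36 ± 0.16 at 28425440 to 28425845 of chromosome 2, another peak than the one named for LPS), monocyte identity (43 and 49 of 128, adjusted p = 0.796) and housekeeping genes (15 and 13 of 47, adjusted p = 0.952) were not called as lists. Their counts adjusted over the list alone were 35 and 57, 65 and 38, 50 and 69, 43 and 49, and 15 and 13. Not called either were the markers of T cells (adjusted p = 0.703), B cells (0.402), NK cells (0.855), granulocytes (0.511), or platelets and erythroid cells (0.399). The promoter peaks of CXCL10 (3.43 ± 0.15), IL1B (2.60 ± 0.11), SOCS3 (1.71 ± 0.12), TNF (0.67 ± 0.11) and IRF1 (0.45 ± 0.07) rose. Those of IRF5 (-0.48 ± 0.09) and IRF8 (-0.24 ± 0.09, adjusted p = 0.0221) fell. That of IL6 was not called (0.08 ± 0.20, adjusted p = 0.739). The call of IRF8 was lost with library weights (adjusted p = 0.0501). It was also lost without Rest replicate 3 (0.0558), Rest replicate 4 (0.0587) or TNF replicate 1 (0.0715). In all, 24652 peaks rose and 24809 fell (23489 and 23476 with the replicate block), 10388 and 6685 of them by at least 1 (8189 and 8507 after quantile normalization).

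The LPS and TNF responses overlapped. Of the peaks called in both, 21945 rose with both stimuli, against 9034 for independent lists of these sizes, and 22607 fell with both, against 9611, while 203 rose with LPS and fell with TNF and 286 did the opposite. Log2 changes correlated across peaks by 0.925, with a covariance of 1.13. Simulated groups without an effect that shared the Rest libraries gave 0.503 and 0.0157, and separate pairs of Rest libraries for each comparison gave correlations of 0.888 and 0.917.

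**Figure D2:**
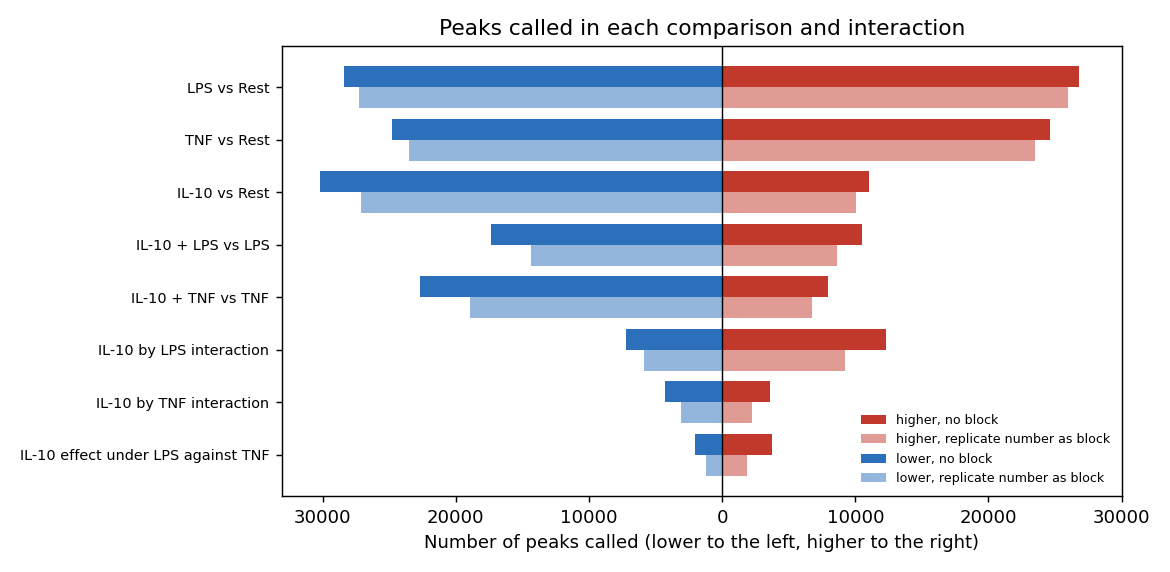
Number of peaks called higher (right of 0) and lower (left of 0) in each of the 5 comparisons and 3 interactions, without a block and with the replicate number as a block. LPS against Rest has 26827 higher and 28358 lower peaks, and with IL-10 alone 30186 peaks are lower and 11060 higher as deposited, against 13018 and 13161 after quantile normalization.

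IL-10 against Rest asks what IL-10 does by itself. The largest openings were next to CYTH4 (5.97 ± 0.25, 62.9-fold, adjusted p = 4.92e-16, limma; chromosome 22, 37280695 to 37281124) and inside ALOX5, the gene of the lipoxygenase that starts leukotriene synthesis (5.78 ± 0.24). Others were nearest CLDN34 (5.74 ± 0.16), PTPN2, which encodes a phosphatase acting on JAK and STAT proteins (5.49 ± 0.27), and NOS2 (5.01 ± 0.23, 22736 bp away). The largest falls were near ZFP36L2 (-4.21 ± 0.23) and CD9 (-3.86 ± 0.18), inside FCN1, a monocyte lectin gene (-3.73 ± 0.29), and at CCDC152 (-3.57 ± 0.43) and AFF3 (-2.77 ± 0.39).

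Known IL-10 and STAT3 response genes opened, with 134 of 293 peaks higher and 51 lower (134 and 51 adjusted over the list alone), led by SOCS3 (3.39 ± 0.10) and the kinase gene PIM1 (4.14 ± 0.17). The IL-10 and STAT3 list had camera adjusted p = 3.96e-15, and adjusted p = 0.115 with an estimated correlation. Antigen presentation genes closed, with 87 of 130 peaks lower and 5 higher (92 and 6 adjusted over the list alone), including peaks near B2M, the class I light chain (-1.09 ± 0.11), and HLA-DMA (-1.58 ± 0.17). The antigen presentation list had camera adjusted p = 1.22e-05, and adjusted p = 0.218 with an estimated correlation. The list median of antigen presentation genes was -0.48, a difference of -0.25 from the median of all peaks, and after centring on the library median 71 of their peaks were lower and 9 higher.

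The NF-kB list was called higher relative to other peaks (camera adjusted p = 0.0145, and adjusted p = 0.704 with an estimated correlation), with 55 peaks higher and 65 lower of 218, a median of -0.06 and a mean of 0.01. Its rises included BCL3 (4.25 ± 0.18), a nuclear inhibitor of NF-kB, and TNIP3 (1.68 ± 0.09). Tissue-resident type macrophage genes (33 higher and 20 lower of 115; median -0.01, mean 0.11; MERTK 0.97 ± 0.09, VSIG4 3.50 ± 0.35) and glycolysis genes (39 and 37 of 138; median -0.02, mean 0.05) were also called higher relative to other peaks. Camera gave them adjusted p = 0.0014 and adjusted p = 0.0029, but adjusted p = 0.482 and adjusted p = 0.275 with an estimated correlation. These 3 lists had the same counts adjusted over the list alone. After centring on the library median they were 72 and 43, 42 and 16, and 54 and 23. BCL3, TNIP3, MERTK and VSIG4 are also on the list of known IL-10 and STAT3 response genes. The calls of the NF-kB and macrophage lists are therefore not fully separate from the call of that list. Over all peaks, log2 changes rose with mean accessibility in this comparison (correlation 0.275). Random lists of like mean were not drawn for these lists, so their calls may follow this trend in part.

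Interferon-stimulated genes were not called as a list with IL-10 alone (105 of 217 peaks lower and 18 higher, median -0.35, camera adjusted p = 0.248), although the antiviral gene OAS2 had a peak that fell (-1.23 ± 0.11) and IRF9 one that rose (1.35 ± 0.10). Inflammatory genes (29 higher and 52 lower of 158, adjusted p = 0.323) had rises near IL27 (1.26 ± 0.11) and CXCL1 (1.57 ± 0.16) but were not called. Interferon regulatory factors (12 and 32 of 85, adjusted p = 0.975; IRF2 1.52 ± 0.17), the AP-1 and MAF family (23 and 56 of 152, adjusted p = 0.975; FOSL2 1.12 ± 0.07, JUND -0.78 ± 0.09), monocyte identity (22 and 52 of 128, adjusted p = 0.975) and housekeeping genes (11 and 12 of 47, adjusted p = 0.0545) were not called either. With adjustment over the list alone, the counts of these 6 lists, in this order, were 18 and 105, 29 and 50, 11 and 31, 23 and 56, 22 and 53, and 11 and 10. After centring on the library median, rises outnumbered falls at inflammatory (36 and 31), NF-kB pathway (72 and 43) and housekeeping genes (19 and 8). Rises and falls were then near equal at interferon regulatory factors (19 and 22) and monocyte identity genes (31 and 32), while falls led in the AP-1 and MAF family (42 and 32) and at interferon-stimulated genes (72 and 33). Marker lists of T cells (9 higher and 24 lower of 41, adjusted p = 0.549), B cells (0.240), NK cells (0.725), granulocytes (0.701), and platelets and erythroid cells (0.151) were not called.

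Among promoter peaks, SOCS3 (2.34 ± 0.12) and IL1B (0.43 ± 0.11) rose with IL-10 alone, and IRF5 (-0.71 ± 0.09, adjusted p = 2.16e-07), TNF (-0.55 ± 0.11) and CXCL10 (-1.03 ± 0.15) fell. A pseudocount of 5 ended the call of CXCL10 (-0.12, adjusted p = 0.104). The fall at IRF1 (-0.18 ± 0.07, adjusted p = 0.0338) was not called with the block (adjusted p = 0.0544), or after centring on the library median (-0.04, adjusted p = 0.682). Nor was it called without Rest replicate 2 (adjusted p = 0.119), Rest replicate 3 (0.0524), IL-10 replicate 1 (0.0762) or IL-10 replicate 4 (0.0636). IRF8 (0.17 ± 0.09, adjusted p = 0.120) and IL6 (0.09 ± 0.20) were not called. Centring brought IRF8 past the threshold (0.30, adjusted p = 0.0091). So did leaving out IL-10 replicate 2 (adjusted p = 0.0431) and quantile normalization (0.0465). In all, 11060 peaks rose and 30186 fell (10085 and 27103 with the block), and 73.2% of the calls were lower. That share was 54.7% after centring on the library median (16315 higher and 19678 lower) and 49.7% after quantile normalization. The median change of all peaks was -0.23, so the falls are relative to the deposited scale. At a log2 change of at least 1 there were 2025 higher and 2689 lower peaks, but 2612 and 1488 after centring and 2357 and 673 after quantile normalization, which turns the majority.

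IL-10 with LPS against LPS asks which part of the LPS response IL-10 alters. Accessibility fell most inside LIPA, which encodes lysosomal acid lipase (-4.79 ± 0.34, 27.6-fold, adjusted p = 9.54e-11, limma; chromosome 10, 89308979 to 89310769), and inside IDO1, an interferon-induced enzyme of tryptophan breakdown (-3.83 ± 0.31; chromosome 8, 39917056 to 39917792). Falls near BAALC (-3.53 ± 0.46), in the antiviral gene RSAD2 (-3.49 ± 0.35) and in the receptor gene SLAMF7 (-3.43 ± 0.32) followed. The largest rises were smaller: peaks nearest RPAP3 (2.54 ± 0.25, 40762 bp away), ADM, the gene of the vasodilator peptide adrenomedullin (2.42 ± 0.18), PTPN2 (2.37 ± 0.27), VPS8 (2.25 ± 0.18) and CYTH4 (2.20 ± 0.25).

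Interferon-stimulated genes closed: 186 of 217 peaks fell and 2 rose (190 and 3 adjusted over the list alone), with a median of -1.11, as at MX1 (-2.71 ± 0.13) and OASL (-2.11 ± 0.11). The interferon-stimulated list had camera adjusted p = 2.27e-45, and adjusted p = 4.25e-04 with an estimated correlation. Interferon regulatory factors had 51 of 85 peaks lower and 7 higher (51 and 8 adjusted over the list alone), with a peak 650 bp from IRF1 (-2.95 ± 0.16; chromosome 5, 132480507 to 132481412) and a peak in IRF5 (-0.79 ± 0.06; chromosome 7, 128938838 to 128940843) falling. The interferon regulatory factor list had camera adjusted p = 7.24e-07, and adjusted p = 0.0734 with an estimated correlation. NF-kB pathway genes had 100 of 218 peaks lower and 11 higher (109 and 12 adjusted over the list alone), as at TNFAIP3, which encodes the inhibitor A20 (-2.04 ± 0.15), and TRAF1 (-0.97 ± 0.07). The camera adjusted p was 1.43e-06, but adjusted p = 0.347 with an estimated correlation, and with 1 peak per gene the list pointed the other way (adjusted p = 0.595). Antigen presentation genes had 52 of 130 peaks lower and 8 higher (56 and 9 adjusted over the list alone), including B2M (-1.75 ± 0.11) and NLRC5 (-1.50 ± 0.14). The antigen presentation list had camera adjusted p = 2.22e-04, and adjusted p = 0.275 with an estimated correlation. Markers of T cells moved with these groups, with 22 of 41 peaks lower and 0 higher (25 and 0 adjusted over the list alone). The T cell list had camera adjusted p = 8.69e-04, and adjusted p = 0.275 with an estimated correlation. Only 7 of its 12 genes had a peak. Of its peaks, 13 at 2 genes were induced by LPS, and 10 of these were lowered. Whether the share of T cells differed was not tested.

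Tissue-resident type macrophage genes opened, with 43 of 115 peaks higher and 3 lower (45 and 3 adjusted over the list alone, 31 and 2 with the block), as at MAF (1.30 ± 0.17) and STAB1 (0.47 ± 0.07). The macrophage list had camera adjusted p = 9.6e-07, and adjusted p = 0.275 with an estimated correlation. Inflammatory genes were not called as a list (51 lower and 21 higher of 158, camera adjusted p = 0.174, but called lower within 5 kb of a gene end, adjusted p = 0.0047), although peaks at IL27 (-3.31 ± 0.18) and at PTGS2, the cyclooxygenase-2 gene (-2.99 ± 0.26), fell. Nor were known IL-10 and STAT3 response genes (56 higher and 86 lower of 293, adjusted p = 0.708; S100A9 1.04 ± 0.09, SBNO2 -0.85 ± 0.07), the AP-1 and MAF family (33 and 37 of 152, adjusted p = 0.593; JUN 0.42 ± 0.04, ATF3 -1.46 ± 0.13), glycolysis (26 and 35 of 138, adjusted p = 0.913), monocyte identity (20 and 31 of 128, adjusted p = 0.568) or housekeeping genes (11 and 11 of 47, adjusted p = 0.557). Adjusted over the list alone, the higher and lower counts of these 6 lists, in this order, were 25 and 54, 58 and 94, 36 and 38, 27 and 36, 20 and 32, and 11 and 11. Centring turned the majority to higher for the AP-1 and MAF family (42 and 33), glycolysis (31 and 26) and monocyte identity genes (31 and 24). Markers of B cells (adjusted p = 0.607), NK cells (0.399), granulocytes (0.399), and platelets and erythroid cells (0.323) were not called.

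Promoter peaks of CXCL10 (-1.48 ± 0.15), TNF (-1.01 ± 0.11), IRF1 (-0.54 ± 0.07, adjusted p = 1.68e-06) and IRF5 (-0.50 ± 0.09, adjusted p = 5.14e-05) fell. That of IRF8 (-0.23 ± 0.09, adjusted p = 0.0435) was not called with the block (adjusted p = 0.0779), after quantile normalization (0.114) or after centring (-0.17, adjusted p = 0.168). Nor was it called without LPS replicate 1 (adjusted p = 0.100), 2 (0.0876) or 4 (0.0671) or IL-10 with LPS replicate 1 (0.0918), 3 (0.123) or 4 (0.100). Those of IL6 (-0.45 ± 0.20, adjusted p = 0.0716), IL1B (0.21 ± 0.11) and SOCS3 (-0.10 ± 0.12) were not called. The fall at IL6 was called without LPS replicate 4 (-0.68, adjusted p = 0.0070), without IL-10 with LPS replicate 3 (-0.55, adjusted p = 0.0464) and with a pseudocount of 5 (-0.30, adjusted p = 0.0254). In all, 10497 peaks rose and 17339 fell (8665 and 14380 with the block), 597 and 2449 by at least 1. Lower peaks made up 62.3% of the calls, and 48.9% after centring (14070 higher and 13491 lower).

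**Figure D3:**
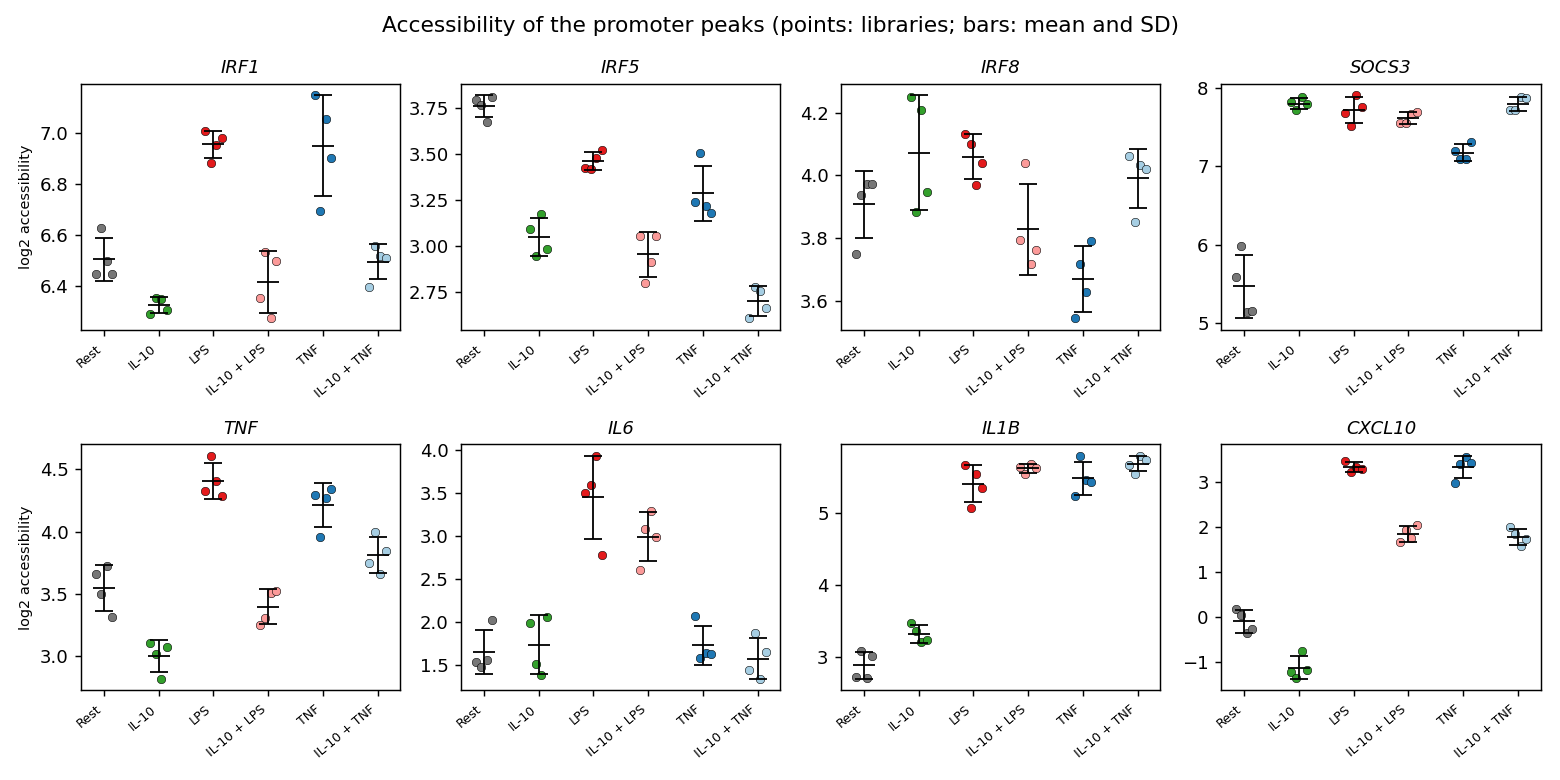
Accessibility (log2 normalized value) at 8 promoter peaks in the 6 groups; each point is a library, and bars show the mean and SD of 4 libraries. CXCL10 rises by 3.43 with LPS and with TNF and changes by -1.48 and -1.55 when IL-10 is added, whereas the changes of IL1B, 0.21 in each case, are not called as deposited (0.36 when added to TNF, called, after centring on the library median).

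Of the 13872 peaks that LPS induced, IL-10 lowered 6763, or 48.8% (95% exact binomial interval 47.9 to 49.6, which covers counting of peaks alone), and raised 687. Among all other peaks 17.8% were lowered. The shares were 42.3% and 12.7% after centring and 44.4% and 10.9% after quantile normalization. Because both comparisons use the LPS libraries, the share was also computed with separate LPS libraries for each, which gave 42.1% and 30.5%, against 14.9% and 10.9% of other peaks. Peaks at interferon-stimulated genes were lowered most often, in 130 of 139 induced peaks (93.5%, against 48.3% of the other induced peaks; odds ratio 15.5, Fisher's exact test, two-sided, adjusted p = 2.97e-29 over 32 tests). Interferon regulatory factors (22 of 29, adjusted p = 0.0238) and antigen presentation genes (12 of 14, adjusted p = 0.0283) were also lowered more often by this test, while inflammatory genes (42 of 94, adjusted p = 0.883) and NF-kB pathway genes (75 of 132, adjusted p = 0.177) were not. With the block the interferon-stimulated (adjusted p = 3.62e-33) and antigen presentation lists (0.0114) were called, and the interferon regulatory factors were not (17 of 29, adjusted p = 0.302). Only with the block was the AP-1 and MAF family called (19 of 28, adjusted p = 0.0422, without it 0.0771). Peaks of 1 gene are not independent in these tests. The log2 changes of the 2 comparisons correlated across peaks by -0.49, as in simulated groups that share the LPS libraries (-0.50), with a covariance of -0.27 against -0.0155.

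IL-10 with TNF against TNF asks the same for TNF. Among the largest falls were peaks inside THBS1, which encodes the matrix glycoprotein thrombospondin-1 (-3.94 ± 0.31, 15.4-fold, adjusted p = 4.83e-10, limma; chromosome 15, 39597557 to 39599725), next to FBXO39 (-3.64 ± 0.23), inside LIPA (-3.44 ± 0.21) and near RIGI, which encodes a cytosolic RNA sensor (-3.40 ± 0.35). The largest rises were nearest C2CD4A (3.64 ± 0.20; chromosome 15, 62087646 to 62088343), inside the potassium channel gene KCNJ15 (3.57 ± 0.32), and next to PTPN2 (3.18 ± 0.27), CYTH4 (2.93 ± 0.25) and SCYGR5 (2.90 ± 0.13).

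Interferon-stimulated genes again closed, with 182 of 217 peaks lower and 3 higher (188 and 4 adjusted over the list alone), a median of -0.91, and falls at OAS2 (-2.62 ± 0.11) and MX1 (-2.98 ± 0.13). The interferon-stimulated list had camera adjusted p = 7.51e-32, and adjusted p = 0.0019 with an estimated correlation. Antigen presentation genes had 84 of 130 peaks lower and 2 higher (90 and 2 adjusted over the list alone), as at B2M (-1.78 ± 0.11) and the class II transactivator CIITA (-1.13 ± 0.13). The antigen presentation list had camera adjusted p = 2.1e-09, and adjusted p = 0.0801 with an estimated correlation. Inflammatory genes had 78 of 158 peaks lower and 6 higher (80 and 7 adjusted over the list alone), with CXCL8 (-2.49 ± 0.14) and LTA (-0.71 ± 0.08) falling. The inflammatory list had camera adjusted p = 7e-04, but adjusted p = 0.465 with an estimated correlation and adjusted p = 0.877 with 1 peak per gene. Interferon regulatory factors had 42 of 85 peaks lower and 7 higher (48 and 9 adjusted over the list alone), including peaks at IRF1 (-2.59 ± 0.16) and IRF5 (-0.90 ± 0.06). The interferon regulatory factor list had camera adjusted p = 0.0083, and adjusted p = 0.308 with an estimated correlation. T cell markers fell beside them in 23 of 41 peaks with 0 higher (23 and 0 adjusted over the list alone). The T cell list had camera adjusted p = 0.0031, and adjusted p = 0.308 with an estimated correlation. Of its peaks, 9 at 3 genes were induced by TNF, and 2 of these were lowered. The share of T cells was not tested here either.

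Known IL-10 and STAT3 response genes opened with 106 of 293 peaks higher and 46 lower (108 and 50 adjusted over the list alone), as at SOCS3 (1.65 ± 0.12) and STAT3 (0.39 ± 0.03). The IL-10 and STAT3 list had camera adjusted p = 1.47e-10, and adjusted p = 0.221 with an estimated correlation. Tissue-resident type macrophage genes (25 higher and 22 lower of 115; CD163 1.26 ± 0.17, MAF 1.01 ± 0.14), glycolysis genes (38 and 26 of 138; median -0.04, mean 0.05) and housekeeping genes (15 and 9 of 47) were called higher relative to other peaks. In camera they had adjusted p = 8.69e-04, adjusted p = 2.77e-04 and adjusted p = 5.91e-04. With an estimated correlation these became adjusted p = 0.465, adjusted p = 0.159 and adjusted p = 0.132. Adjusted over the list alone, the counts were 24 and 20, 39 and 29, and 16 and 10. With the block they were 23 and 12, 32 and 19, and 14 and 7. After centring on the library median they were 36 and 7, 55 and 10, and 23 and 6. CD163 is also on the list of known IL-10 and STAT3 response genes. Over all peaks, log2 changes rose with mean accessibility here too (correlation 0.316). Random lists of like mean were not drawn for these lists, so their calls may follow this trend in part. NF-kB pathway genes (29 higher and 90 lower of 218, adjusted p = 0.402, but called higher with 1 peak per gene, adjusted p = 6.43e-04; TNFAIP2 -1.40 ± 0.12, TNIP3 0.81 ± 0.09), the AP-1 and MAF family (22 and 51 of 152, adjusted p = 0.792; ATF3 -1.48 ± 0.13, MAFF -1.43 ± 0.14) and monocyte identity genes (17 and 35 of 128, adjusted p = 0.546) were not called. These counts became 31 and 96, 24 and 52, and 17 and 35 adjusted over the list alone. Centring turned the majority of the AP-1 and MAF family (36 higher, 28 lower) and of monocyte identity genes (29 and 15). Markers of B cells (adjusted p = 0.272), NK cells (0.643), granulocytes (0.725), and platelets and erythroid cells (0.643) were not called.

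Promoter peaks of CXCL10 (-1.55 ± 0.15), IRF5 (-0.58 ± 0.09) and IRF1 (-0.46 ± 0.07) fell and those of SOCS3 (0.62 ± 0.12) and IRF8 (0.32 ± 0.09, adjusted p = 0.0061) rose. The fall at TNF (-0.40 ± 0.11, adjusted p = 0.0037) was not called after centring (-0.25, adjusted p = 0.0743). IL1B (0.21 ± 0.11) and IL6 (-0.15 ± 0.20) were not called, as deposited. Centring (0.36, adjusted p = 0.0142), library weights (0.24, adjusted p = 0.0423) or leaving out TNF replicate 2 (0.31, adjusted p = 0.0269) brought IL1B past the threshold. In all, 7930 peaks rose and 22696 fell (6722 and 18894 with the block), and 74.1% of the calls were lower. By at least 1 there were 742 and 1804 as deposited, 1117 and 1061 after centring, and 1614 and 1081 after quantile normalization. After centring on the library median 14541 rose and 11897 fell, so that 45.0% were lower. The median change of all peaks was -0.18 as deposited.

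Of the 10388 peaks that TNF induced, IL-10 lowered 3400, or 32.7% (95% exact binomial interval 31.8 to 33.6), and raised 1242, while 30.7% of other peaks were lowered. This near equality depends on the scaling, since the shares were 21.9% and 15.3% after centring and 23.6% and 13.0% after quantile normalization. With separate TNF libraries in each comparison the shares were 23.7% and 22.6%, which is 1.65 and 1.22 percentage points above other peaks. Induced peaks at interferon-stimulated genes were lowered in 92 of 102 cases (90.2%, against 32.2% of other induced peaks; Fisher's exact test, two-sided, adjusted p = 1.52e-32 over 32 tests). Inflammatory genes (50 of 95, adjusted p = 6.69e-04) and NF-kB pathway genes (56 of 123, adjusted p = 0.0226) were lowered more often than other induced peaks. Induced peaks at known IL-10 and STAT3 response genes were lowered less often (13 of 88, with 29 raised, adjusted p = 0.0017). These 4 lists were also called with the block (adjusted p = 2.41e-36, 5.38e-04, 0.0252 and 0.0040). Only with the block were antigen presentation genes (8 of 12, adjusted p = 0.0319, without it 0.0807) lowered more often and glycolysis genes (2 of 27, adjusted p = 0.0419, without it 0.0550) less often. The effects of IL-10 under LPS and under TNF shared no libraries and correlated across peaks by 0.635, with 11004 peaks lower in both (5376 for independent lists) and 4540 higher in both (1137).

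**Figure D4:**
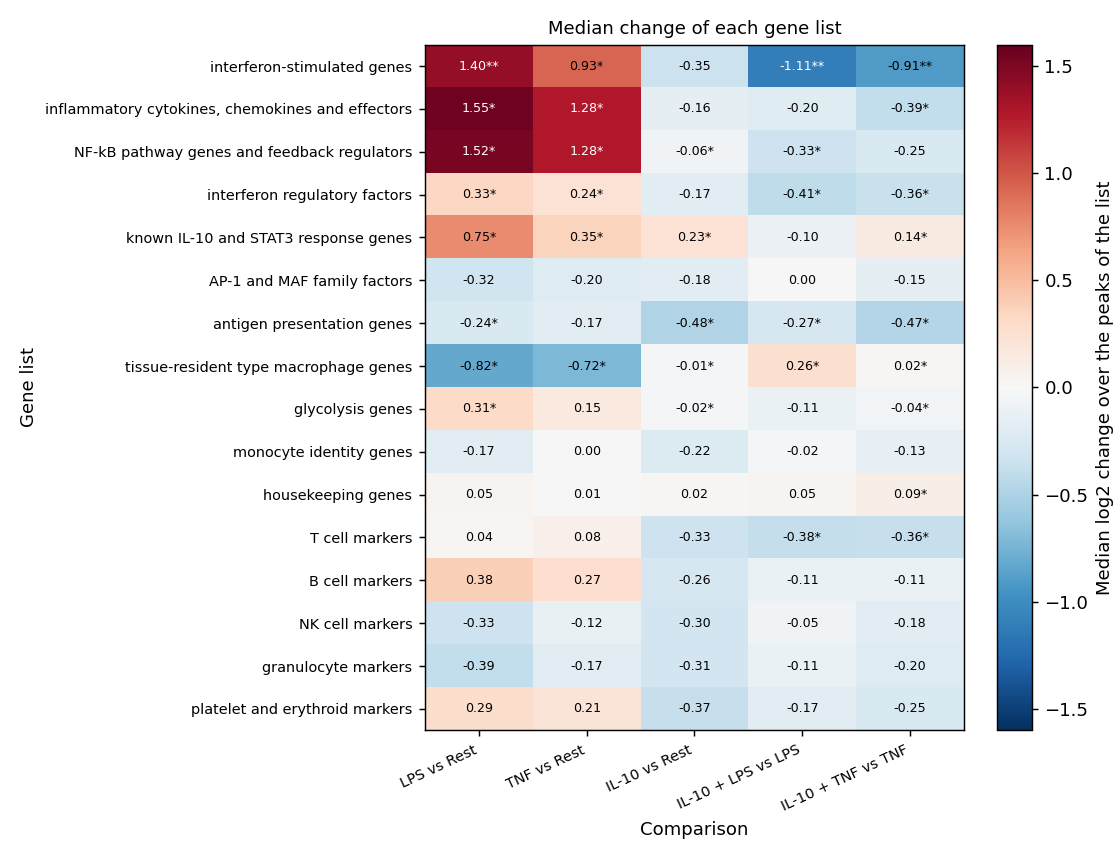
Median log2 change over the peaks of each gene list (vertical) in each comparison (horizontal), coloured from blue (lower) to red (higher); 1 star marks a camera adjusted p under 0.05 and a pair of stars one that also holds with an estimated correlation. The interferon-stimulated list has medians of 1.40 with LPS, -1.11 when IL-10 is added to LPS and -0.91 when it is added to TNF.

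The interactions ask where the effect of IL-10 differs between stimulation states. Each is a departure from additive log2 effects, so it can also arise where a stimulus alone had already closed or opened the peak. Under LPS the effect was lower than in unstimulated cells near MYO1G (-2.66 ± 0.12), CLDN34 (-5.07 ± 0.23) and SOCS3 (-3.16 ± 0.15, adjusted p = 4.39e-14, limma), where IL-10 alone had opened the latter by 3.39. It was higher near CD9 (3.23 ± 0.26), in ADTRP (1.12 ± 0.09) and near ZFP36L2 (1.34 ± 0.12; chromosome 2, 43219503 to 43220416). LPS alone and IL-10 alone had each lowered the CD9 peak, so the higher effect there does not mean that IL-10 opened it. In all, 12288 peaks had a higher and 7241 a lower effect (9255 and 5864 with the block). Higher effects made up 62.9% of these calls, and 51.6% after centring (9431 and 8844). The majority turned to lower after centring with the block (7042 and 7089) and at a log2 change of at least 1 (1966 and 2756).

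Under TNF the effect was lower near MYO1G (-2.13 ± 0.12), CLDN34 (-4.03 ± 0.23) and NCEH1 (-2.77 ± 0.17), and higher in ADTRP (1.08 ± 0.09), near ZFP36L2 (3.79 ± 0.32, at another peak, 43221040 to 43221558) and in SULF2 (1.63 ± 0.14), with 3602 peaks higher and 4298 lower. With the block these were 2236 and 3072, and a pseudocount of 5 turned the majority to higher (5892 and 5364). Between the stimuli, the effect of IL-10 was higher under LPS nearest RAB4A (3.09 ± 0.24), in KIF1B (1.22 ± 0.13) and near DAPK2 (0.96 ± 0.11), and lower in FNIP2 (-2.37 ± 0.19), near ELL2 (-1.38 ± 0.11) and in LITAF (-1.18 ± 0.11). The counts were 3772 higher and 2037 lower without the block and 1837 and 1216 with it. They were 2172 and 2890 after centring, which turned the majority from higher to lower, as did a pseudocount of 5 (3546 and 3798), a log2 change of at least 1 (473 and 752) and centring with the block (1069 and 1708). They were 6231 and 2825 without TNF replicate 1. Without IL-10 with LPS replicate 3 the higher count was 2395.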

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

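The tests of library scaling, of signal over background across all peaks, of TNF replicate 1, of separate LPS libraries, and of the interactions with additive effects taken out were chosen only after the result was seen.

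In 17 of 336 sets of 4 libraries at the peaks named here (5.06%, where chance gives about 5%), 1 library lay far from the others of its group. The gap to the nearest library, as a share of the range of the group, is given for each. In the Rest group it was 0.945 at CD9 (replicate 4 highest), 0.849 at TNIP3 (replicate 3 highest), 0.840 at the IRF8 promoter (replicate 1 lowest), 0.855 at the IL6 promoter (replicate 4 highest), 0.865 at TNFAIP8 (replicate 2 highest), 0.889 at IRF2 (replicate 2 highest) and 0.844 at MERTK (replicate 3 highest). In the LPS group it was 0.927 at EGR1 (replicate 1 highest), 0.909 at CYTH4 (replicate 3 highest) and 0.859 at JUN (replicate 4 lowest). In the TNF group it was 0.867 at SOCS3 (replicate 3 lowest), 0.897 at the IL6 promoter (replicate 1 highest) and 0.926 at LTA (replicate 1 lowest). With IL-10 and LPS it was 0.869 at PTPN2 (replicate 3 highest) and 0.845 at TNFAIP3 (replicate 4 highest), and with IL-10 and TNF 0.848 at IRF1 (replicate 3 highest) and 0.874 at CLDN34 (replicate 4 lowest). No library had over 2 of these.

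Peaks were called for a different effect of IL-10 between stimulation states by a test of the difference itself (limma interactions). Whether chance gives as many calls is weighed below. Against unstimulated cells, 12288 peaks had a higher and 7241 a lower effect under LPS, including CD9 (3.23), ADTRP (1.12), ZFP36L2 (1.34), MYO1G (-2.66), CLDN34 (-5.07) and SOCS3 (-3.16). Under TNF these counts were 3602 and 4298, including ADTRP (1.08), another peak near ZFP36L2 (3.79), SULF2 (1.63), MYO1G (-2.13), CLDN34 (-4.03) and NCEH1 (-2.77). Between LPS and TNF they were 3772 and 2037, including RAB4A (3.09), KIF1B (1.22), DAPK2 (0.96), FNIP2 (-2.37), ELL2 (-1.38) and LITAF (-1.18). These are departures from additive log2 effects, which can also arise where a stimulus alone had already closed or opened the peak.

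For each of the 5 comparisons, 35 splits of the 8 libraries into groups of 4 were fitted, and the real split gave the most calls, so chance is excluded if libraries are exchanged freely. The real count was 55185 against a highest other of 12836 for LPS against Rest, 49461 against 20616 for TNF, 41246 against 96 for IL-10, 27836 against 1 for IL-10 with LPS, and 30626 against 8170 for IL-10 with TNF. Each was reached by 1 of 35 splits. Only 8 of these part as many replicate numbers, too few for a share under 0.05; the real split was the highest of them, and the others exchange the libraries of some numbers between the groups.

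For the interactions, labels were drawn 100 times within each stimulation state. As many calls as the real 19529 were found in 1 of 100 draws under LPS (highest other 15435). Between LPS and TNF 4 of 100 draws gave as many as the real 5809 (highest other 25610). For IL-10 by TNF, 5 of 100 draws gave as many as the real 7900 (highest other 28737), so chance is not excluded by this test. Draws with several times the real count moved libraries of 1 state more than those of the other, so that the effect of IL-10 itself entered the contrast, which is a structure of these samples. All these draws exchange libraries as if IL-10 had no effect in either state, and they ignore the pairing. They therefore cannot decide whether chance gives as many differences between states. In a second set of 100 draws over 16 libraries, with the additive effects taken out first, 1 of 100 reached the real count in each interaction, with a highest other of 8177, 1832 and 0. That scheme was chosen because of the first result and does not replace it, so whether chance gives these counts stays open for each interaction.

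The first pattern weighed is that more peaks were called lower than higher when IL-10 was present. After centring each library on its median, at most 54.7% of the calls were lower in any of the 3 IL-10 comparisons, but centring moves the medians itself, so library scaling and a broad loss of accessibility cannot be told apart by it. The weakest peaks fell more than the strongest in all 3 (smallest difference of medians 0.334 log2). The values sum to nearly the same total over the peaks in every library. Less signal over background would then raise weak peaks against strong ones. These values therefore argue against it over all peaks, although the rule written for this test had read the same difference the other way. They argue only against less signal over background with IL-10. A technical difference in the other direction was not tested. The trend with mean cannot be the whole source of the falls near interferon-stimulated genes. Under LPS or TNF, 0 of 10000 random peak lists of like mean had a median as low as theirs (-1.11 and -0.91 against random lows of -0.25 and -0.31). Such lists were drawn for the interferon list alone, so other list calls with IL-10 were not freed of this trend. A biological loss of accessibility across many sites, through the IL-10 treatment the design names, was not tested apart from these.

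The second pattern is that TNF replicate 1 stands apart, with an SD of its deviations from the group mean of 0.304 (TNF replicate 2 0.280, all others 0.157 to 0.228). The counts of TNF against Rest and of IL-10 with TNF against TNF do not rest on it, since they changed by a factor of at most 1.06 without it in the blocked fit. The count of peaks where IL-10 acts differently under LPS and TNF changed by a factor of up to 2.41 (1837 to 4434 higher and 1216 to 2124 lower), so that count may be set in part by 1 library. Its deviations correlated by -0.48 to -0.14 with those of replicate 1 in the other groups, and by 0.15 to 0.24 with those of replicate 2. The strongest value was -0.73, with TNF replicate 2. The removed term per number fixes part of such values. No explanation, biological or of the numbering of these libraries, was tested.

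The third pattern is that IL-10 lowered LPS-induced peaks more often than other peaks, also after centring (42.3% against 12.7%) and quantile normalization (44.4% against 10.9%). The LPS libraries shared by both comparisons are excluded as its source, since with separate libraries the difference was at least 19.6 percentage points. Induced peaks were also lowered 30.5 points more often than other peaks of like mean. That mean is over all 24 libraries and not the level with LPS, and both comparisons shared the LPS libraries there. This difference therefore cannot exclude less signal over background as a source. Over all peaks the trend with mean argued against that source, as described for the first pattern, but the trend was not examined within the induced peaks. Within the pattern, stronger induction near interferon-stimulated genes is excluded, since random induced peaks of like induction and mean reached at most 68.3% lowered against 93.5% there. An effect of IL-10 on interferon-driven opening may underlie part of it. That is a hypothesis drawn from these same libraries, and whether interferon drives the opening was not tested.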

How the results depend on the processing

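The combination of centring with the block, and the fits with the block and without TNF replicate 1 or 2, were added after the data were seen. Depth is unknown, so its effect on low peaks could not be weighed; a count test on whole reads and the motif shares were not run, because no whole reads or genome sequence were used here. Of 181 calls at named peaks, 176 held in each alternative run on them but the fold threshold. Removal of the lowest peaks left 162 of the 191 named results to test. The calls that did not hold are at the promoters of IRF1, IRF8, TNF and CXCL10. Apart from the promoters, named peaks were picked by the size of their change or their p in these same data. Their share of held calls therefore does not speak for called peaks in general. The replicate block ended the calls of the IRF1 promoter (IL-10 against Rest, adjusted p = 0.0544) and the IRF8 promoter (IL-10 with LPS against LPS, adjusted p = 0.0779). It changed no other call of a named peak, and it left all 80 list calls as they were. Values below follow the order higher, lower, and where nothing else is said the cause was not tested.

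With the block, the IL-10 by TNF interaction had 2236 higher, and that of LPS against TNF 1837 and 1216 (1698 higher without TNF replicate 2 as well); the block leaves fewer degrees of freedom. A log2 change of at least 1, a stricter threshold by construction, gave 13872 and 11244 for LPS, 10388 and 6685 for TNF, 2025 and 2689 for IL-10, 597 and 2449 for IL-10 with LPS, 742 and 1804 for IL-10 with TNF, and 1966 and 2756, 643 and 1393, and 473 and 752 for the interactions with LPS, with TNF and between them. At this threshold, centring turned the majority for IL-10 (2612 and 1488) and IL-10 with TNF (1117 and 1061), as did quantile normalization (2357 and 673, and 1614 and 1081), which also turned it for LPS (11839 and 13131) and TNF (8189 and 8507). Centring left 19678 lower for IL-10, 14541 and 11897 for IL-10 with TNF, and 2172 higher between LPS and TNF. Centring with the block left 16776 lower for IL-10, 11195 lower for IL-10 with LPS, 12614 and 9441 for IL-10 with TNF, 7042 and 7089 by LPS, and 1069 and 1708 between LPS and TNF. Quantile normalization left 13018 lower for IL-10, 15080 and 11930 for IL-10 with LPS, 10392 lower for IL-10 with TNF and 3546 lower between LPS and TNF. Library weights gave 6779 and 3447 between LPS and TNF, and a pseudocount of 5 gave 5892 and 5364 by TNF and 3546 and 3798 between them, which turns both majorities.

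The share of LPS-induced peaks lowered by IL-10 was 43.3% with the block, 50.5% and 59.3% with pseudocounts of 0.1 and 5, 43.5% without the lowest peaks, 44.4% after quantile normalization, 42.3% after centring (37.5% with the block too), 53.9% with library weights, 51.3% in a fit of the groups compared, 41.3% with induction by adjusted p alone, 15.2% for a fall of at least 1, and 42.1% and 30.5% with separate LPS libraries. For TNF these were 28.7%, 33.8% and 35.9%, 29.6%, 23.6%, 21.9% (18.7%), 36.0%, 29.7%, 32.9% (not moved), 8.56%, and 23.7% and 22.6%; with the block and without TNF replicate 1 or 2 they were 28.7% and 29.9%.

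Leaving out 1 library gave ranges of 2395 to 6231 higher for the interaction between LPS and TNF (highest without TNF replicate 1, lowest without IL-10 with LPS replicate 3), 40.3% to 49.6% for the LPS share and 26.4% to 33.7% for the TNF share. No other count moved by over 1.5 times from its value with all libraries.

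Of the 5 comparisons, lists were called in as many as follows. With an estimated correlation the interferon-stimulated list kept 3 of 4, and the inflammatory, NF-kB, interferon regulatory factor, IL-10 and STAT3, antigen presentation, macrophage, glycolysis, housekeeping and T cell lists had 0 (without it 3, 4, 4, 4, 4, 5, 3, 1 and 2). With 1 peak per gene there were 0 for interferon regulatory factors, 2 for IL-10 and STAT3, 1 for AP-1 and MAF, 2 for monocyte identity, 3 for housekeeping and 0 for T cells. Within 5 kb of a gene end there were 2, 1, 2 and 0 for interferon regulatory factors, AP-1 and MAF, housekeeping and T cells. With fry, which does not compare a list with other peaks, there were 3 each for AP-1 and MAF, macrophage, housekeeping, B cell, NK cell and granulocyte lists, 2 for monocyte identity, and 5 each for T cells and platelets.

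Calls lost with 1 peak per gene were interferon regulatory factors with LPS (adjusted p = 0.465), TNF (0.632), IL-10 with LPS (0.332) and IL-10 with TNF (0.874), IL-10 and STAT3 genes with LPS (0.0513) and TNF (0.0649), antigen presentation with LPS (0.465), inflammatory (0.877) and macrophage genes (0.159) for IL-10 with TNF, and T cell markers for IL-10 with LPS (0.697) and with TNF (0.632). Within 5 kb the lost calls were interferon regulatory factors with LPS (0.205) and TNF (0.986), antigen presentation (0.104) and glycolysis with LPS (0.107), and T cell markers for IL-10 with LPS (0.0638) and with TNF (0.374). Calls gained by lists were, with 1 peak per gene, AP-1 and MAF (adjusted p = 0.0285) and housekeeping (0.0247) for IL-10, monocyte identity (0.0051) and housekeeping (0.0031) for IL-10 with LPS, and monocyte identity (9.56e-04) for IL-10 with TNF. Within 5 kb they were inflammatory genes for IL-10 with LPS (0.0047) and AP-1 and MAF for IL-10 (0.0258).

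Among lists called before or after the change of setting, directions reversed in these cases; reversals of lists called in neither are not listed. With 1 peak per gene: NF-kB under IL-10 with LPS (adjusted p = 0.595) and IL-10 with TNF (6.43e-04), and glycolysis with LPS (0.877) and IL-10 with LPS (0.0028). With fry: interferon regulatory factors (3.5e-04), AP-1 and MAF (5.74e-05) and monocyte identity (2.58e-04) for IL-10, and AP-1 and MAF (3.2e-04), monocyte identity (0.0124), NK cell (0.0262) and granulocyte markers (0.0331) for IL-10 with TNF. Within 5 kb: housekeeping genes with TNF (0.0490). The IL6 promoter, not called in these comparisons, turned to 0.11 for IL-10 with TNF after quantile normalization. For TNF it turned to -0.043 with library weights, -0.033 without TNF replicate 1 and -0.055 with the block too. For IL-10 it turned to -0.022 without IL-10 replicate 4. Without Rest replicate 4, which lay apart there, it was 0.20 for TNF and 0.21 for IL-10, not called.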

Other observations

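The contrast of LPS with TNF was chosen only after the data were seen.

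LPS and TNF shared most of their response, yet differed at named sites. The largest excess with LPS was next to ACOD1, the gene of the enzyme that makes itaconate (4.52 ± 0.24 log2, 22.9-fold, adjusted p = 1.97e-13, limma, n = 4 per group; chromosome 13, 76958307 to 76960204), followed by peaks near ATP6V1C1 (3.98 ± 0.40), ZC3HAV1, which encodes an antiviral zinc finger protein (3.98 ± 0.17), AEBP2 (3.74 ± 0.22) and BAALC (3.69 ± 0.44, 31529 bp away). Accessibility was lower with LPS than with TNF inside TMEM138 (-3.35 ± 0.32) and THBS1 (-3.08 ± 0.31), and at peaks nearest RAB4A (-3.02 ± 0.17, 44156 bp away), HLA-DQB1 (-2.19 ± 0.37, 23758 bp away) and the chemokine gene CXCL3 (-2.18 ± 0.24, 813 bp away). In all, 11541 peaks were higher and 14439 lower with LPS (9965 and 12132 with the replicate block), 2758 and 1062 by at least 1. After centring, 13088 were higher and 12600 lower, so over all calls neither direction leads on every scale. The real split gave 25980 calls against at most 10953 in the other splits of these libraries, and 1 of 35 reached it, so chance is excluded if libraries are exchanged freely. Only 8 splits part as many replicate numbers, too few for a share under 0.05.

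Interferon-stimulated genes were more open with LPS than with TNF, with 118 of 217 peaks higher and 5 lower (camera adjusted p = 7.27e-15 over 16 lists, and adjusted p = 0.0341 with an estimated correlation). Known IL-10 and STAT3 response genes (149 higher and 38 lower of 293, adjusted p = 1.23e-12) and NF-kB pathway genes (84 and 20 of 218, adjusted p = 6.47e-06) were also higher, and antigen presentation genes lower (19 and 58 of 130, adjusted p = 0.0023), but with an estimated correlation these gave adjusted p = 0.142, adjusted p = 0.272 and adjusted p = 0.272. Glycolysis genes (46 and 13 of 138) were higher with adjusted p = 5.18e-05, and adjusted p = 0.127 with an estimated correlation. Also called were housekeeping genes, higher (12 and 2 of 47, adjusted p = 0.0331), and tissue-resident type macrophage genes (13 and 37 of 115, adjusted p = 0.0346) and granulocyte markers (2 and 14 of 34, adjusted p = 0.0190), lower. With an estimated correlation these 3 gave adjusted p = 0.272, adjusted p = 0.563 and adjusted p = 0.286. Inflammatory genes were not called as a list (32 and 51 of 158, adjusted p = 0.404).

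On the deposited scale, the TNF-induced peaks as a whole showed no excess of lowering by IL-10 beside other peaks of like mean (32.7% against 33.3%, a difference of -0.55 percentage points). Against all other peaks the shares were 21.9% and 15.3% after centring and 23.6% and 13.0% after quantile normalization, so an excess depends on the scaling. Within them, peaks at interferon-stimulated genes were lowered in 90.2%, above all of 10000 random lists of TNF-induced peaks of like induction and mean, which reached at most 50%. With IL-10 alone the median of the interferon list (-0.35) was lower than in all but 78 of 10000 random lists of like mean. These lists leave out the correlation between peaks of a list, and the list was not called by camera (adjusted p = 0.248, and adjusted p = 0.787 with an estimated correlation).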
